A study of Mus musculus with 6 samples.

How the data were processed

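The samples were 6 poly(A) RNA libraries from clonal fibroblast lines, 3 het and 3 knockout for Macf1, made with a stranded mRNA kit per the labels' protocols. Per the submitters' processing notes, the tools named are Trimmomatic 0.36, kallisto 0.42.5 and edgeR (version not given), with genome build GRCm38.p4. The authors deposited estimated counts per transcript for 96626 transcripts, which need not be whole (48.2% of the values were not). They also deposited FPKM values for 24799 transcripts. Of these, 24794 had an FPKM above 1 in at least 3 samples. The authors' deposited comparison holds a log2 fold change, a log2 mean CPM, a p-value and an adjusted p-value per transcript, per the file headers.

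Transcripts were assigned to genes with the GENCODE M21 annotation of GRCm38. Of the 96626 transcripts, 95213 matched it, 260 were assigned through the authors' deposited table, and 1153 had no match and were left out. These held 0.017% to 0.028% of the counts of a sample. Estimated counts were summed over the transcripts of each gene, giving 32028 genes, of which 20543 had a count above 0, and were rounded to whole numbers. Reads shared between near-identical genes are divided by estimation, so pseudogenes and gene copies are uncertain. Among the tested genes, 38 had counts identical to those of another gene in all 6 samples, and 12 of these passed. Xist and Tsix were not found among these genes.

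Genes were kept with edgeR's filterByExpr (count minimum 10, total minimum 15), scaled with TMM and tested with the robust quasi-likelihood F test in edgeR 4.0.16 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 12745 genes. Standard errors of log2 fold changes were derived from the F statistic. CPM values use the TMM-scaled library sizes, except for Y-linked genes, which use the library totals. Pooled folds compare summed counts, with exact 95% intervals that cover counting error only, as do the floors of 3 counts. That floor corresponds to 0.0595 CPM over the het group and 0.0577 CPM over the knockout group. Per library it is 0.165 to 0.192 CPM.

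Before the data were examined, 44 gene lists were fixed, and 42 had at least 5 tested members. They were tested against all other genes with camera (limma 3.58.1, preset correlation 0.01), with adjustment over the 42 lists. Of these, 12 passed, 11 lower and 1 higher in the knockout clones. With an estimated correlation 0 passed (smallest adjusted p 0.225), and with fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, 23 passed. Genes named in the text followed a rule fixed at the same time. Macf1 and Dst were always named. The 10 highest and 10 lowest fold changes were taken among passing genes with at least 5 CPM in the higher group, clones of the genotypes not overlapping, and a regular gene symbol outside the Y chromosome. From each list up to 4 passing members with the smallest adjusted p were eligible, and the 2 most abundant others where fewer than 2 passed. Exceptions are marked where they occur.

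Gene results were also computed, where the gene was kept, with DESeq2 1.42.0, limma-voom, RLE scaling, library totals, 2 other filters on low counts, a test against a fold of 1.5, limma on log2(FPKM + 1) and log2(FPKM + 0.1), transcripts as units, leaving out each clone, and leaving out genes on chromosomes X and Y. The lists were tested again with RLE scaling, library totals, the 2 other filters, both FPKM scales and each clone left out, besides the estimated correlation and fry, where at least 5 members were kept. The procedure was tested on simulated counts with the means, dispersions and library sizes of these samples and 200 changed genes. For knockout against het, with 12565 genes tested, it recovered 1.5% of genes changed 1.5-fold, 29.9% of those changed 2-fold and 83.3% of those changed 4-fold, with 2 calls among unchanged genes. In the real data 3585 genes passed, far more than in the simulation, and the adjustment is less strict where more genes change. These shares therefore do not give the recovery in the real data. Small changes that were not called can still be present. Libraries of the same genotype differed by more than sampling noise (chi-square per degree of freedom 12.5 to 74.2), so none was treated as a repeat run of the same library. Separate libraries of the same clone would differ by more than sampling noise too, so this does not show that the clones arose independently. Knockout replicates 1 and 2 were the closest pair (12.5, correlation of log2 CPM 0.991).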

Results

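Poly(A) RNA was sequenced from SV40 large T-immortalized fibroblast lines derived from mouse embryos that carried loxP-flanked Macf1 alleles. Macf1 encodes a giant spectraplakin that links actin filaments to microtubules. The cells had been exposed to an adeno-associated virus carrying Cre recombinase, and colonies were raised from single cells. There were 6 libraries: 3 clones with 1 recombined and 1 intact Macf1 allele (het), and 3 clones with both alleles recombined (knockout). The labels of each sample give the genotype of the mice, Macf1flox/+ for the het and Macf1flox/flox for the knockout clones. By these labels no embryo gave clones of both genotypes. The state after Cre is given by the protocol for the whole series. The estimated counts of het replicates 1, 2 and 3 totalled 16972123, 17614982 and 15661342, and those of knockout replicates 1, 2 and 3 totalled 17420060, 16581833 and 18209673. Counts above 0 were found for 17177 to 17447 genes in the het clones and for 16292 to 17190 genes in the knockout clones. The sources do not say how many embryos or parental cultures gave the clones of each genotype, or whether these clones arose independently. The p-values therefore measure the spread between clones and not between embryos.

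The first question was what became of the targeted gene. Macf1 (ENSMUSG00000028649; chromosome 4, 123349633 to 123684360, minus strand, GRCm38) fell in the knockout clones from 656 ± 66.6 to 331 ± 27.9 CPM (counts scaled to a common library size; mean ± SD, n = 3 clones each). The het clones stood at 693, 696 and 579 CPM and the knockout clones at 309, 363 and 322 CPM. The log2 fold change was -0.99 with a standard error of 0.13 (adjusted p = 0.00307, edgeR quasi-likelihood test), and all 3 knockout clones lay below all 3 het clones. Dst, the other large spectraplakin gene (ENSMUSG00000026131; chromosome 1, 33908225 to 34308661), stood at 781 ± 78.6 CPM in het and 800 ± 58.5 CPM in knockout clones (log2 fold change 0.04, adjusted p = 0.861, edgeR). Counts were also resolved by Macf1 transcript, of which 10 of 16 annotated ones were tested. The most abundant was Macf1-215, which has 90 exons and begins at position 123544831. It fell from 359 ± 60 to 97.6 ± 11 CPM (log2 fold change -1.88, SE 0.17, adjusted p = 0.00432, edgeR on transcripts). Macf1-212, which begins further upstream at 123664752, fell from 6.42 ± 1.83 to 0.435 ± 0.149 CPM (adjusted p = 0.00794, edgeR on transcripts). The next most abundant transcript, with 70 exons, begins further downstream at 123499917. It measured 109 ± 8.47 CPM in het and 116 ± 0.532 CPM in knockout clones (log2 fold change 0.09, adjusted p = 0.637, edgeR on transcripts). The other 7 tested transcripts did not pass. Among them, 5 that begin downstream of 123499917 had log2 fold changes of -1.22, -0.55, -0.5, -0.39 and 0.41, and 2 that begin upstream of it had -1.1 and -2.15. The transcript at -1.22 had an adjusted p of 0.0807 here (edgeR on transcripts) and of 0.0325 in the authors' deposited table. Transcripts of 1 gene share most of their exons, so their separate levels are estimates. Which exons lie between the loxP sites is not given in the sources used here, so a level over the whole gene does not by itself check the recombination.

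**Figure D1:**
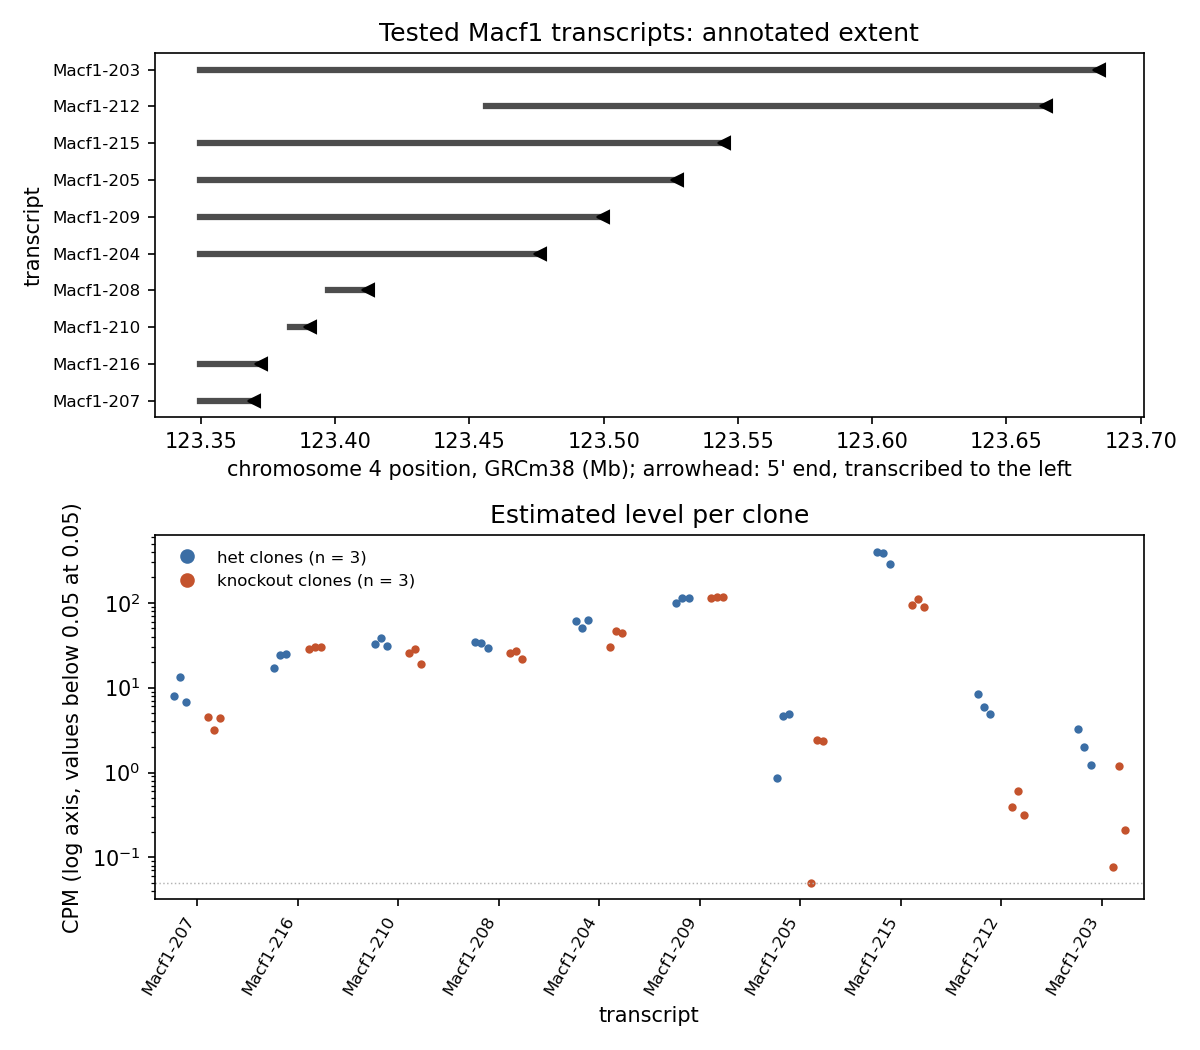
Annotated extent of the 10 tested Macf1 transcripts on chromosome 4 (GRCm38, Mb; upper panel) and their estimated level in each clone (CPM, log axis; lower panel; blue points het, orange points knockout, 3 clones each, values below 0.05 drawn at 0.05). Macf1-215 and Macf1-212 were lower in all 3 knockout clones, while the transcript of 70 exons stood at a mean of 109 CPM in het and 116 CPM in knockout clones.

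Gene expression differed widely between the genotypes. Of 12745 genes tested, 3585 (28.1%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. Of these, 1771 were higher and 1814 lower in the knockout clones. This balance depended on the setting, with 1884 higher and 1353 lower on log2(FPKM + 1) with limma, and 1240 higher and 1829 lower with local chromosome medians taken out, a setting chosen after seeing the data. Changes of at least 2-fold were more often losses, with 1056 genes lower and 476 higher. The clones of the 2 genotypes did not overlap in 3579 of the passing genes, and in 47.5% of all genes tested, against 10% by chance for 3 clones against 3. Correlations of log2 CPM across genes, which are not independent replicates, were 0.974 to 0.991 among knockout clones and 0.853 to 0.87 between genotypes. Among het clones, replicates 2 and 3 correlated at 0.981, and replicate 1 correlated with them at 0.947 and 0.94. The count of passing genes was 2227 without het replicate 2, 1892 without knockout replicate 1 and 1566 without knockout replicate 2.

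The genes with the greatest losses were silent or nearly so in every knockout clone. Trim44, a tripartite-motif protein gene (chromosome 2, 102300119 to 102407828), had no counts in knockout clones against 110 ± 55.9 CPM in het clones, at least 1900-fold lower. Folds against a group without counts are bounds set by a floor of 3 counts over the 3 libraries of the group. The same pattern was seen for Hoxa11 (at least 1030-fold lower), Arsj, an arylsulfatase gene (at least 914-fold), Ebf3, a transcription factor gene (at least 823-fold), Ifi202b, an interferon-inducible gene (at least 721-fold), Cyba, which encodes the p22phox subunit of NADPH oxidase (at least 647-fold), Hoxd11 (at least 566-fold) and Ctsc, which encodes the protease cathepsin C (at least 436-fold). Fbn2, which encodes the microfibril protein fibrillin-2, had 1 count in all knockout clones together, a 15100-fold difference with a counting interval of 2710 to 596000. Igsf10 likewise had 1 count (5300-fold, interval 950 to 209000). All of these passed in edgeR, with adjusted p from 5.9e-05 for Arsj to 0.023 for Hoxd11. Fbn2 and Igsf10 ranged widely among het clones (297 ± 326 and 105 ± 116 CPM), and each lost its call with limma-voom (adjusted p = 0.322 and 0.0655). Without knockout replicate 1 the call also ended for Fbn2, Igsf10 and Hoxd11 (edgeR adjusted p = 0.0834, 0.0685 and 0.0562). It ended for Fbn2 without knockout replicate 2 or 3 (0.0837 and 0.128), and for Hoxd11 without het replicate 2 or knockout replicate 2 or 3 (0.0628, 0.0528 and 0.0523). With no filter on low counts, Fbn2 and Hoxd11 did not pass either (0.0698 and 0.107). The log2 fold change of Fbn2 was -13.45, and -12.16 without het replicate 3 or -15.27 without knockout replicate 3. That of Igsf10 was -11.95, and -10.53 without het replicate 3 or -13.82 without knockout replicate 1.

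Other genes were expressed almost only in the knockout clones. Wnt5a, which encodes a ligand of non-canonical Wnt signalling (chromosome 14, 28504750 to 28527448), stood at 15.2 ± 1.84 CPM in knockout clones and had 1 count in the het clones together (764-fold higher, counting interval 137 to 30200; adjusted p = 0.000138, edgeR). Ildr2, an immunoglobulin-like domain receptor gene, rose 388-fold to 125 ± 21.9 CPM. Col4a6, which encodes a collagen IV chain of basement membranes, rose 218-fold to 59.8 ± 13.2 CPM (14 het counts, counting interval 130 to 399). Irx1, a homeobox gene, had no counts in het clones and was at least 136-fold higher in knockout clones. Il24, a cytokine gene, was at least 118-fold higher but varied between knockout clones (7.42 ± 6.46 CPM). Hoxc5, Hoxc6, Hoxc4 and Hoxc8 rose 2280-fold (1 het count, interval 409 to 90100), 424-fold, 259-fold and 169-fold. The pseudogene Rpl15-ps2 also rose (2950-fold, 1 het count, interval 529 to 117000), but its reads cannot be told with certainty from those of Rpl15. All 10 passed in edgeR, with adjusted p from 3.14e-05 for Hoxc4 to 0.029 for Il24. Il24 lost its call without het replicate 2 or 3 or knockout replicate 1 or 2 (edgeR adjusted p = 0.0556, 0.0508, 0.0711 and 0.0882), or with no filter on low counts (0.0847). Its bound of 118-fold became at least 66.1-fold without knockout replicate 1 and at least 180-fold without knockout replicate 3. Without het replicate 1 the log2 fold change went from 7.71 to 8.88 for Col4a6 and from 8.59 to 9.18 for Ildr2. It went from 10.69 to 12.56 for Hoxc5 and from 11.09 to 12.97 for Rpl15-ps2 without het replicate 2, and from 9.13 to 11.04 for Wnt5a without het replicate 3.

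The title of the series concerns the formation of cilia and apicobasal polarity, and the machinery of both was examined as gene lists. Genes of intraflagellar transport (IFT) and its motors, which carry cargo along the cilium, showed little difference: of 31 tested members, 2 were higher, 1 was lower and 28 did not pass (2 higher and 0 lower adjusted over the list alone). Wdr35, an IFT-A subunit, rose from 59.1 ± 2.21 to 94.6 ± 12.5 CPM (log2 fold change 0.68, SE 0.12, adjusted p = 0.00728, edgeR). Dync2h1, the heavy chain of the retrograde motor, fell from 40.4 ± 9.56 to 25.2 ± 0.233 CPM (adjusted p = 0.0277, edgeR), but its direction turned in the deposited FPKM values (log2 difference 0.05 on log2(FPKM + 1), adjusted p = 0.822, limma). For the BBSome and ciliary membrane trafficking, 7 of 34 members rose, 2 fell and 25 did not pass (9 higher and 2 lower adjusted over the list alone). Ttc8, a BBSome subunit also called BBS8, rose from 15.4 ± 1.42 to 30.8 ± 7.03 CPM, and Tulp3, which brings receptors into the cilium, fell from 86.7 ± 1.01 to 47 ± 3.05 CPM (adjusted p = 0.0094 and 0.00135, edgeR). In the transition zone, the gate at the ciliary base, 4 of 31 members rose, 4 fell and 23 did not pass (4 and 4 adjusted over the list alone). Iqcb1 rose from 29.8 ± 2.47 to 54.1 ± 5.36 CPM, and Cc2d2a fell from 30.9 ± 13.2 to 12.4 ± 0.428 CPM (adjusted p = 0.00347 and 0.0178, edgeR). Among centriole and basal body genes, 3 of 42 rose, 7 fell and 32 did not pass (2 higher and 5 lower adjusted over the list alone). Kif24 fell from 30.7 ± 0.829 to 19.4 ± 1.66 CPM and Cep250 from 177 ± 5.74 to 124 ± 9.46 CPM (adjusted p = 0.00663 and 0.00838, edgeR). None of these 4 lists was shifted in 1 direction against the other genes with camera, with adjusted p of 0.539, 0.267, 0.655 and 0.81 and median log2 fold changes of 0.09, 0.1, 0.08 and -0.07. The form of fry that counts changes in either direction gave adjusted p of 0.00282, 8.07e-06, 8.07e-06 and 6.11e-05. It does not compare a list with other genes, and 28.1% of all tested genes passed singly. Cc2d2a lost its call without knockout replicate 1, 2 or 3 (edgeR adjusted p = 0.0711, 0.0715 and 0.0508), and Dync2h1 without het replicate 3 or knockout replicate 1, 2 or 3 (0.0533, 0.0831, 0.0949 and 0.06). Wdr35 and Ttc8 lie on chromosome 12, where most genes were higher in the knockout clones, and did not pass with the local chromosome median taken out (0.0594 and 0.0625). Wdr34, the other IFT gene that rose, lies on chromosome 2 at 30031546 and did not pass in that setting either (edgeR adjusted p = 0.126). The same held for Arl3 of the BBSome and trafficking list, on chromosome 19 (0.0911). Iqcb1 lies on chromosome 16, where most genes were also higher, and still passed in that setting. Its log2 fold change was 0.86, and as low as 0.51 among the alternatives. The lists were not tested with the local chromosome median taken out.

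Signalling by Hedgehog depends on the cilium in mammals, and mRNA of its components and targets was tested as 1 list. Of 26 tested members, 12 fell, 0 rose and 14 did not pass (12 lower and 0 higher adjusted over the list alone), with a median log2 fold change of -0.66. The list was lower with camera (adjusted p = 3.47e-06), and this call was lost with an estimated correlation (adjusted p = 0.225). Osr1, a transcription factor gene, fell from 22.8 ± 8.22 to 0.0376 ± 0.0329 CPM (2 knockout counts, 586-fold, counting interval 162 to 4850). The cyclin genes Ccnd2 and Ccnd1 fell 296-fold and 30.3-fold, the latter from 100 ± 28.7 to 3.41 ± 1.27 CPM. Gas1, a Hedgehog co-receptor gene, fell 72.2-fold (log2 fold change -6.21, and -7.26 without knockout replicate 3). Adjusted p were 0.000225, 0.000369, 0.000576 and 0.00131 (edgeR). Gli2 and Gli3, which encode the main transcription factors of the pathway, and Smo and Ptch1, which encode its signal transducer and receptor, were chosen after their values were seen. Gli2 had no counts in knockout clones against 9.7 ± 7.16 CPM (at least 167-fold lower, and at least 111-fold without het replicate 3), and Gli3 fell from 127 ± 8.41 to 78.4 ± 9.72 CPM (adjusted p = 0.0134 and 0.00666, edgeR). Smo measured 124 ± 13 CPM in het and 141 ± 2.8 CPM in knockout clones, and Ptch1 70.5 ± 26.7 and 47.8 ± 3.61 CPM (adjusted p = 0.211 and 0.144, edgeR; Ptch1 passed without het replicate 1, 0.0374).

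More apicobasal polarity genes rose than fell, with 13 of 36 higher, 3 lower and 20 not passing (14 higher and 3 lower adjusted over the list alone). Mpp5, which encodes the Crumbs-complex scaffold PALS1, rose from 33.6 ± 0.808 to 85.8 ± 8.38 CPM (log2 fold change 1.35, SE 0.1, adjusted p = 0.000524, edgeR). It lies on chromosome 12, in a stretch of 40 genes with a median log2 fold change of 0.51. Its call held in all 18 alternatives, including the local chromosome median taken out, with log2 fold changes of 0.84 to 1.42. Mark1, a polarity kinase gene, rose from 5.3 ± 1.62 to 22.7 ± 3.69 CPM, Llgl2 from 8.41 ± 0.531 to 19.8 ± 3.02 CPM and Magi2 from 2.46 ± 0.977 to 12.4 ± 1.78 CPM. The list did not pass (median log2 fold change 0.07, adjusted p = 0.051 with camera, 0.292 with an estimated correlation), but it passed without het replicate 2 or 3 or knockout replicate 1 or 2 (camera adjusted p = 0.0425, 0.0413, 0.0226 and 0.045). In planar cell polarity, which orients cells within a sheet, 6 of 30 members rose, 6 fell and 18 did not pass (6 and 7 adjusted over the list alone; camera adjusted p = 0.866, median -0.17). Wnt5a rose, as given above. In contrast, Daam2 fell from 21.4 ± 12.4 to 0.969 ± 0.267 CPM and Ror2, a Wnt5a receptor gene, from 34.9 ± 4.2 to 17.1 ± 2.64 CPM (adjusted p = 0.00334 and 0.00478, edgeR). Of 44 plakins and microtubule plus-end proteins, 5 rose, 13 fell and 26 did not pass (6 and 14 adjusted over the list alone; camera adjusted p = 0.0754, median -0.12). Clip4 fell from 25.5 ± 5.21 to 0.0409 ± 0.0354 CPM (2 knockout counts, 660-fold, counting interval 182 to 5460), and Ppl, which encodes periplakin, fell 117-fold from 17.8 ± 4.21 CPM (adjusted p = 7.02e-05 and 7.39e-05, edgeR). This list passed without het replicate 1 (adjusted p = 0.0485, camera).

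**Figure D2:**
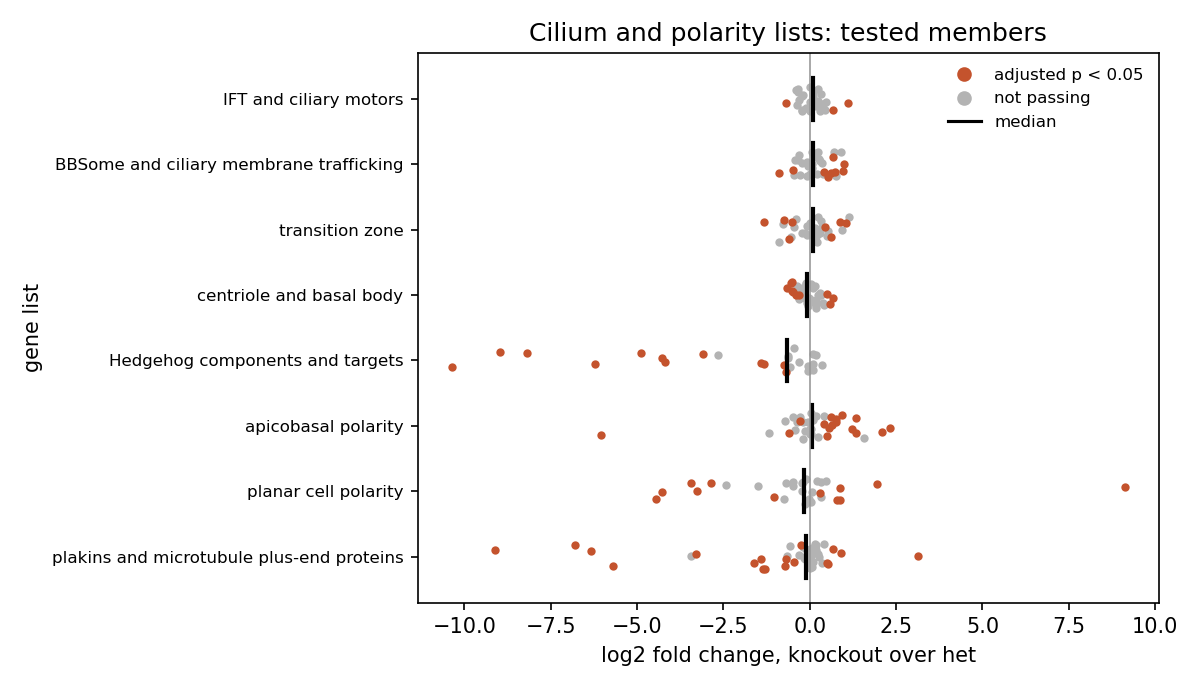
Log2 fold change of knockout over het clones for every tested member of the 8 cilium and polarity lists (orange, adjusted p under 0.05 in edgeR; grey, not passing; black bar, median; vertical scatter is random). The Hedgehog list has a median of -0.66, while the medians of the other lists lie between -0.17 and 0.1.

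Positional identity genes differed between the genotypes in both directions. Of 52 tested Hox and other positional genes, 27 rose, 12 fell and 13 did not pass (29 higher and 15 lower adjusted over the list alone; median log2 fold change 1.81). The median was 0.7, 0.99 and 0.94 without knockout replicate 1, 2 and 3, and at most 1.96 with 1 clone left out. In the other alternatives it reached 2.51. Hox genes set position along the body axis and the limb. All 7 tested genes of the Hoxc cluster (chromosome 15, 102921103 to 103036852) and all 8 of the Hoxb cluster (chromosome 11, 96271457 to 96354012) were higher in knockout clones in edgeR. In the Hoxa cluster, 6 rose, 3 fell and 1 did not pass, and in the Hoxd cluster, 3 fell and 3 did not pass. Hoxb9 rose from 2.38 ± 1.96 to 142 ± 5.74 CPM, Hoxa9 fell from 39.4 ± 17.9 to 5.98 ± 1.33 CPM, and Hoxd10 had no counts in knockout clones against 24.4 ± 5 CPM (at least 422-fold lower); these 3 were chosen after their values were seen. The log2 fold change of Hoxb9 went from 5.9 to 6.73 without het replicate 3. Tbx15, a limb and skin mesenchyme transcription factor gene, fell from 248 ± 25.6 to 28.2 ± 1.69 CPM (adjusted p = 3.14e-05, edgeR). Hoxd11 lost its call without het replicate 2 or any 1 knockout clone (adjusted p up to 0.0628). The list was higher with camera (adjusted p = 1.32e-05). With an estimated correlation this was lost (adjusted p = 0.292).

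**Figure D3:**
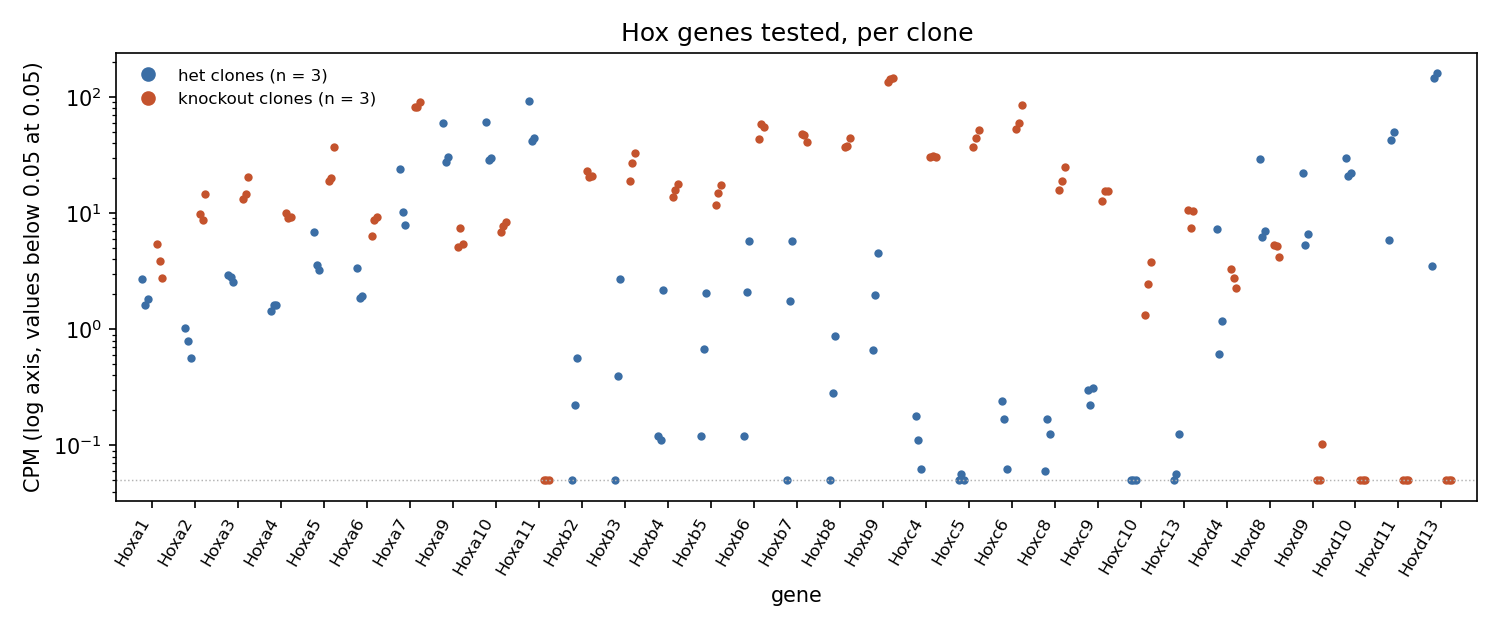
Level of each tested Hox gene in each clone (CPM, log axis; blue points het, orange points knockout, 3 clones each, values below 0.05 drawn at 0.05). Hoxb and Hoxc genes are higher in the knockout clones, and Hoxa11, Hoxd10 and Hoxd11 have no counts there.

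Many genes of the fibrillar extracellular matrix had lower mRNA levels in the knockout clones. Of 42 tested genes, 27 fell, 1 rose and 14 did not pass (28 lower and 2 higher adjusted over the list alone), with a median log2 fold change of -2.73 (-3.44 without knockout replicate 3). Col1a2, which encodes a chain of type I collagen, fell from 1060 ± 786 to 0.816 ± 0.436 CPM, a 1330-fold difference (log2 fold change -10.36, and -9.59 without het replicate 1). Fbn1, which encodes fibrillin-1, fell from 479 ± 96.8 to 17.1 ± 1.22 CPM (log2 fold change -4.81, SE 0.19), Fbln2, a fibulin gene, from 639 ± 307 to 2.53 ± 0.637 CPM, and Lox, which encodes the collagen cross-linking lysyl oxidase, from 453 ± 70.7 to 81.3 ± 24.5 CPM. Adjusted p were 0.00124, 3.38e-05, 0.000247 and 0.00113 (edgeR). Among abundant genes chosen after their values were seen, Thbs1 fell from 4860 ± 1460 to 690 ± 299 CPM and Bgn from 597 ± 446 to 0.615 ± 0.00492 CPM. Fn1, which encodes fibronectin, measured 5770 ± 589 and 4270 ± 294 CPM and did not pass (adjusted p = 0.121, edgeR), although it passed with DESeq2 (adjusted p = 0.00527) and on log2(FPKM + 1) with limma (0.0469). Sparc measured 906 ± 195 and 712 ± 119 CPM (adjusted p = 0.255, edgeR). The list was lower with camera (adjusted p = 1.33e-13). With an estimated correlation this was lost (adjusted p = 0.225).

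**Figure D4:**
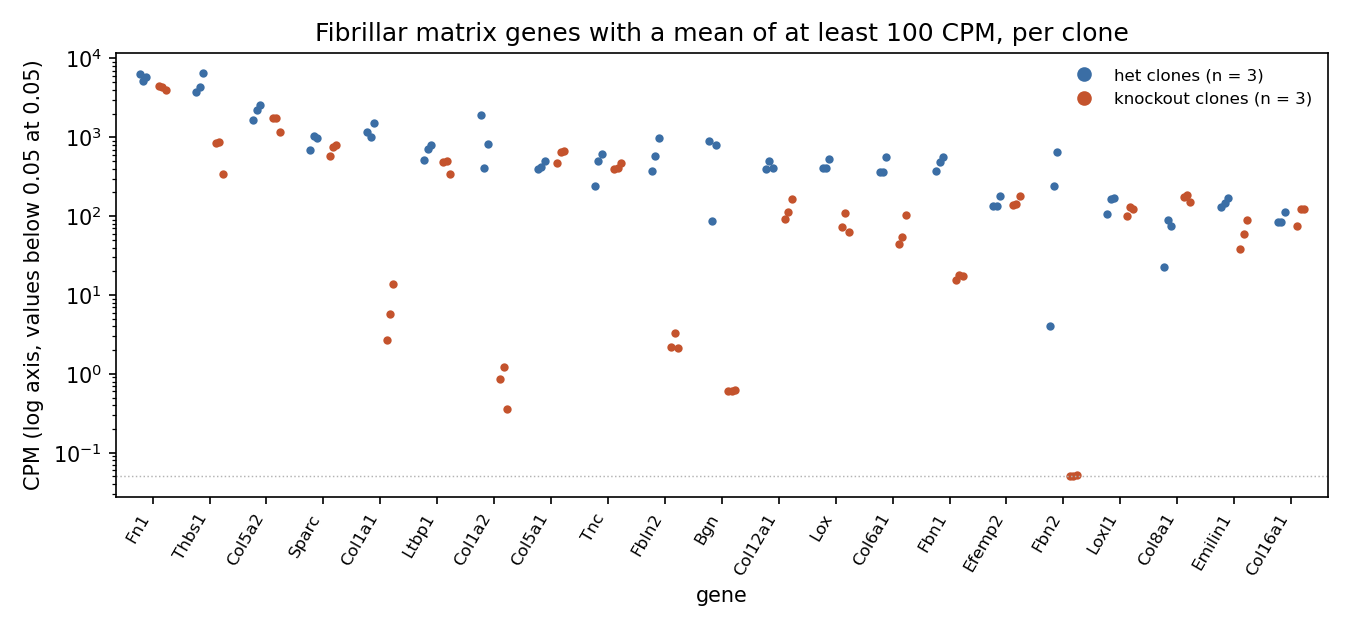
Level of the 21 fibrillar matrix genes with a mean of at least 100 CPM in each clone (CPM, log axis; blue points het, orange points knockout, 3 clones each, values below 0.05 drawn at 0.05). Col1a1, Col1a2, Fbln2, Bgn and Fbn2 are lower by orders of magnitude in the knockout clones, while Fn1 and Sparc overlap or lie close together.

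Among lists of cell type markers, those of fibroblasts and of smooth muscle were lower with camera, and neither call held with an estimated correlation. Of 20 fibroblast and mesenchyme markers, 11 fell, 0 rose and 9 did not pass (2 higher and 11 lower adjusted over the list alone; median log2 fold change -0.75; camera adjusted p = 7.87e-05, and 0.225 with an estimated correlation). Prrx1, a mesenchymal transcription factor gene, fell from 259 ± 114 to 20.4 ± 0.297 CPM, and Twist2 from 31.1 ± 1.45 to 12.8 ± 1.96 CPM (adjusted p = 0.00115 and 0.00199, edgeR). Vim, which encodes vimentin and was chosen after its values were seen, measured 2430 ± 350 and 2870 ± 1110 CPM (adjusted p = 0.612, edgeR). Of 7 smooth muscle and pericyte markers, 4 fell, 1 rose and 2 did not pass (1 higher and 4 lower adjusted over the list alone; median -2.41; camera adjusted p = 1.38e-05, and 0.225 with an estimated correlation). The median of this list ran from -4.32 to -1.66 over 14 alternatives, and from -2.64 to -2.19 with 1 clone left out. Cspg4, which encodes the proteoglycan NG2, fell 1020-fold from 137 ± 18.9 to 0.127 ± 0.129 CPM (log2 fold change -9.93, and -10.97 without knockout replicate 3), Tagln 22.6-fold and Acta2 28-fold. Lists of other cell types did not pass with camera. Adjusted p was 0.0692 for epithelial markers (1 higher, 4 lower of 10), 0.757 for endothelial (1 lower of 6), 0.261 for skeletal muscle (3 higher of 11), 0.622 for neural and glial (1 higher, 3 lower of 8), 0.448 for adipocyte (1 higher, 3 lower of 9) and 0.209 for cartilage and bone markers (2 higher, 5 lower of 12). The epithelial list passed without het replicate 1 (adjusted p = 0.00166) or knockout replicate 1 (0.0499). Its median was -0.26 with all clones, and -0.75 and -0.55 in these fits. It was -0.81 and -0.94 without knockout replicate 2 and 3, where the list did not pass. It also passed with the filter of at least 1 CPM (0.0276), where its median was 0.1, while the test stayed on the lower side. Adjusted over the list alone, 4 cartilage and bone markers were higher and 5 lower, and the counts of the other 5 of these lists were the same as over all genes. Macrophage and blood markers, with 3 genes tested and 1 higher, were too few for the list test.

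The lists of cholesterol synthesis, mitochondrially encoded genes, NRF2 targets and the unfolded protein response were lower with camera, and none of these 4 calls held with an estimated correlation. In cholesterol synthesis, 22 of 29 genes fell, 0 rose and 7 did not pass (23 lower adjusted over the list alone; median log2 fold change -1.08). Fdft1, which encodes squalene synthase, fell from 168 ± 27.7 to 63.5 ± 1.83 CPM, Hsd17b7 from 56.9 ± 11.6 to 21.4 ± 3.32 CPM and Dhcr7, the last reductase of the pathway, from 36.5 ± 9.17 to 13.6 ± 2.68 CPM (adjusted p = 0.000985, 0.00342 and 0.00546, edgeR). The camera test gave adjusted p = 1.84e-07, and 0.564 with an estimated correlation. Of 13 genes encoded by the mitochondrial genome, 9 fell and 4 did not pass (9 lower adjusted over the list alone; median -0.64; camera adjusted p = 0.00307, and 0.564 with an estimated correlation), with mt-Atp8 going from 173 ± 10.8 to 68.3 ± 9.63 CPM. Among NRF2 targets, 9 of 26 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.6; camera adjusted p = 0.00434, and 0.631 with an estimated correlation), and Nqo1, a quinone reductase gene, fell 13.4-fold. Of 30 genes of the unfolded protein and integrated stress response, 11 fell and 3 rose (12 and 3 adjusted over the list alone; median -0.34; camera adjusted p = 0.00729, and 0.564 with an estimated correlation). The amino acid response genes Chac1 and Trib3 fell 8.2-fold and 7.92-fold. That list did not pass without knockout replicate 3 (adjusted p = 0.153).

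The lists of TGF-beta and BMP targets, imprinted genes and Wnt targets were lower with camera, and these calls were lost with an estimated correlation as well. Of 30 TGF-beta and BMP signalling targets, 10 fell and 2 rose (15 and 2 adjusted over the list alone; median log2 fold change -0.74; camera adjusted p = 0.00118, and 0.437 with an estimated correlation). The BMP ligand gene Bmp4 fell 156-fold from 112 ± 34.9 to 0.718 ± 0.0906 CPM (adjusted p = 3.71e-05, edgeR), and Grem1, which encodes a BMP antagonist, fell 27.7-fold. Of 17 imprinted genes, 5 fell and 2 rose (5 and 2 adjusted over the list alone; median -0.39; camera adjusted p = 0.000736, and 0.225 with an estimated correlation). Grb10, a growth inhibitor gene, fell 1330-fold from 358 ± 32.5 to 0.257 ± 0.202 CPM (log2 fold change -10.35, and -11.12 without knockout replicate 3; adjusted p = 3.14e-05, edgeR), and Igf2r, which encodes the receptor that clears IGF2, rose from 151 ± 32 to 421 ± 47.8 CPM (adjusted p = 0.00223, edgeR). Of 17 Wnt beta-catenin targets, 8 fell and 3 rose (8 and 4 adjusted over the list alone; median -0.5; camera adjusted p = 0.0497, and 0.511 with an estimated correlation), among them Ccn5, which fell 107-fold (log2 fold change -6.76, and -6.13 without het replicate 3), and Ccnd1, which also belongs to the Hedgehog list. The imprinted and Wnt lists did not pass without knockout replicate 3, although their medians were then further from 0 (-1 and -0.98; adjusted p = 0.0714 and 0.0684). On the deposited FPKM values they did not pass either (adjusted p = 0.177 and 0.148 on log2(FPKM + 1)), with medians of -0.08 and -0.42. With 1 clone left out the imprinted median ran from -1 to -0.08 and the Wnt median from -0.98 to -0.61. Over all alternatives the Wnt median ran from -1.18 to -0.42. The imprinted median was -0.08 without het replicate 1 and -0.71 without het replicate 2, and the Wnt median was -0.92, -0.81, -0.86 and -0.84 without het replicate 1 or 2 or knockout replicate 1 or 2.

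The remaining lists did not pass with camera. For cytoskeleton and adhesion, adjusted p was 0.0961 for tubulins and stathmins (1 higher, 8 lower of 28), 0.256 for actin and SRF targets (5 higher, 6 lower of 40), 0.0961 for YAP and TAZ targets (2 higher, 6 lower of 29) and 0.879 for focal adhesion and integrins (5 higher, 6 lower of 39). Tubb2b, a beta-tubulin gene, fell 1120-fold from 129 ± 47.4 CPM (6 knockout counts, counting interval 514 to 3050; log2 fold change -10.03, and -11.84 without knockout replicate 1), and Fhl1 fell from 189 ± 20.1 to 32.6 ± 3.9 CPM (adjusted p = 0.000333 and 8.23e-05, edgeR). For the matrix around cells, adjusted p was 0.324 for basement membrane (6 higher, 5 lower of 24) and 0.15 for matrix proteases and inhibitors (5 higher, 9 lower of 35), and Col4a5 rose from 35.8 ± 2.47 to 302 ± 69.1 CPM beside Col4a6. For growth and stress, it was 0.467 for the cell cycle (9 higher, 14 lower of 55), 0.31 for p53 targets (3 higher, 5 lower of 28), 0.221 for immediate early genes (4 higher, 11 lower of 32) and 0.261 for hypoxia and glycolysis (6 higher, 9 lower of 34). For other groups, it was 0.597 for motile cilia (3 higher, 2 lower of 18), 0.117 for cytokines and chemokines (2 higher, 6 lower of 25), 0.467 for MHC class I (2 higher, 1 lower of 19), 0.235 for cytosolic ribosomal proteins (4 higher, 1 lower of 57) and 0.879 for histone genes (1 higher of 10). The 23 tested genes nearest Macf1 on chromosome 4 gave 3 higher and 3 lower (adjusted p = 0.879). No interferon response gene passed among 49 in edgeR, with 1 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma-voom (camera adjusted p = 0.235), and the list passed without het replicate 3 (0.00328) or knockout replicate 1 (0.0132). Adjusted over the list alone, the counts higher and lower were 3 and 7 for YAP and TAZ targets, 7 and 6 for focal adhesion, 9 and 6 for basement membrane, 6 and 9 for matrix proteases, 9 and 17 for the cell cycle, 5 and 12 for immediate early genes, 1 and 0 for MHC class I, 2 and 1 for ribosomal proteins and 0 and 0 for histones. For the other lists of this group they equalled those over all genes. Without het replicate 1, camera called the lists of YAP and TAZ targets (adjusted p = 0.0315), matrix proteases (0.0368), cytokines (0.0368) and ribosomal proteins (0.0315). It also called actin and SRF targets and cytokines without het replicate 3 (0.0413 and 0.0379), YAP and TAZ targets without knockout replicate 1 (0.0386) and ribosomal proteins without knockout replicate 3 (0.000472). With all clones, YAP and TAZ targets passed with no filter on low counts (0.0182), and tubulins and stathmins on log2(FPKM + 0.1) (0.0499). Median and mean, or median and test, had opposite signs for basement membrane, adipocyte, MHC class I, motile cilia, neural and glial, focal adhesion and the genes nearest Macf1.

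Y-linked genes were measured as a check of the lines' origin. In the list of 11 genes with Xist, 9 were found and 3 tested, and none passed in edgeR, although Eif2s3y and Kdm5d passed without het replicate 1 (adjusted p = 1.49e-05 and 0.000196) and with limma-voom (0.0246 and 0.0243). Uty and Ddx3y were chosen after their values were seen. Het replicate 1 expressed Eif2s3y, Kdm5d, Uty and Ddx3y at 78.5, 41.1, 22.3 and 59.1 CPM. Het replicates 2 and 3 stood at or below 3.64 CPM for all 4. The knockout clones expressed Eif2s3y at 148, 158 and 217 CPM, Kdm5d at 56.7, 70 and 107 CPM and Uty at 35.9, 34.9 and 65.4 CPM, but Ddx3y at 0, 0.181 and 0.22 CPM.

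The authors' deposited table compares 24799 transcripts, with positive log2 values for higher levels in the knockout clones. In the authors' deposited table, 3479 transcripts had an adjusted p under 0.05, of which 1594 were higher and 1885 lower. The called transcripts in the authors' deposited table belonged to 2696 genes, 52 of them with calls in both directions, of which 1868 also passed at the gene level here. Of these 1868, 1851 had the same direction as in the authors' deposited table. A gene with calls in both directions there could not count as the same direction, so the rest need not be opposite calls. Both comparisons rest on the same libraries.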

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

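The count of 3585 genes moved by over 1.5 times in 2 settings besides leaving out clones. It was 1100 against a fold of 1.5, a stricter question, and 2299 genes with a called transcript when transcripts were the units. Leaving out 1 clone at a time gave 1566 to 3825 genes, with fewer samples in each fit. The other settings gave 3069 to 4444. The lower figure came with local chromosome medians taken out, a setting chosen after seeing the data. Macf1 kept its direction and its call in all 18 alternatives (log2 fold change -1.07 to -0.54, adjusted p 3.39e-12 to 0.0311). The -0.54 came from log2(FPKM + 1). Gene FPKM values are sums over the 24799 deposited transcripts, each divided by its length. They weigh transcripts otherwise than summed counts do, so the FPKM results measure another quantity. No paired analysis was possible because the replicate numbers only name the clones.

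Of the 42 lists, 12 passed with camera (10 to 18 with 1 clone left out), 0 with an estimated correlation and 23 with fry. The Hedgehog list (median -0.66) did not pass with an estimated correlation. The apicobasal list passed with RLE scaling (median 0.06), no filter (0.06), CPM of at least 1 (0.07) and fry (0.07), and its median ran from 0.06 to 0.17 with 1 clone left out. The plakin list passed with fry (-0.12), and its median ran from -0.15 to -0.03 with 1 clone left out. The BBSome list passed with fry (0.1). The cause was not tested for these. Of 470 alternatives for the other lists, 429 kept the side of the threshold. Some medians near 0 changed sign. Among the genes named or eligible besides Macf1, 3108 of 3334 alternatives kept it, 207 lost the call, 16 gained it and 3 reversed. All 3 were Dync2h1 on log2(FPKM + 1), at 0.05 under either filter, and on log2(FPKM + 0.1), at 0.09; the cause was not tested. Depth limits genes near the floor of 0.165 to 0.192 CPM per library.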

Other observations

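The tests of explanations below were all written after the results were seen.

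Interferon response genes differed between clones of the same genotype. The median over the 49 tested genes, as log2 CPM relative to the mean of the 6 clones, was -2.84, 0.3 and 1.33 in het replicates 1, 2 and 3, and -0.77, 0.42 and 1.63 in knockout replicates 1, 2 and 3. MHC class I and antigen processing genes varied along with them, at -1.49, -0.01 and 0.93 in the het and -0.47, 0.14 and 0.82 in the knockout clones.

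Median fold changes differed between chromosomes. The median log2 fold change of knockout over het was 0.44 for 323 expressed protein-coding genes on chromosome 12, 0.41 for 356 on chromosome 19 and 0.29 for 317 on chromosome 16, and 87.6%, 80.9% and 78.5% of these genes lay above 0. Random sets of the same size, matched on expression, gave medians of -0.02 to 0.09 (95% range), and p was 1e-04 for each of these 3, the smallest that 10000 draws can give (adjusted p = 0.000167 over 20 chromosomes). The same p was found for 12 chromosomes, and 18 of 20 had an adjusted p under 0.05, including chromosome 1 with a median of -0.02 and chromosome 2 with -0.01. The lowest median was -0.13, on chromosomes 13 and 14. Genes are not independent, so these p-values do not separate the shifts of chromosomes 12, 16 and 19 from small ones. Clones of the same genotype also differed, with medians on chromosome 18, relative to the mean of the 6 clones, of 0.3, -0.17 and 0.08 in het and 0.08, 0.01 and -0.27 in knockout replicates 1, 2 and 3. On chromosome 2, the first 6 blocks of 40 genes, up to position 51924448, had medians of 0.28 to 0.66, and the other 14 blocks had medians of -0.22 to 0.02. Chromosome 7 had a median of -0.02 as a whole, but -0.35 to -0.15 in blocks 1 to 8 and 0.16 to 0.32 in blocks 10 to 16. Block 1 of chromosome 10 stood at -0.61 and block 5 of chromosome 8 at 0.44.

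These steps are consistent with gains or losses of chromosomes in immortalized lines, and copy number was weighed as a source of the 3585 differing genes. With the local median of 41 neighbouring genes taken out in each clone, 3069 genes passed, and 2469 of them were among the 3585 with the same direction, which argues against copy number as the whole cause. Of the 10 splits of the clones into 3 against 3, 1, the real one, gave 3585 genes and the highest other 0 (at most 1187 at an unadjusted p under 0.05, edgeR). Every other split put both genotypes in both groups. The genotype difference then widened the spread within groups, which made few calls likely beforehand. The splits therefore cannot tell whether the 3585 genes arose by chance, and 10 are too few for a share under 0.05. The line of origin differed between the genotypes by the labels, with Macf1flox/+ mice for the het and Macf1flox/flox mice for the knockout clones. In addition, 0 het clones had the Y-linked state of the 3 knockout clones (Eif2s3y above 10 CPM, Ddx3y below 1 CPM). The line and the Macf1 genotype therefore cannot be told apart. This confounding covers every difference between the genotypes, among them the Hedgehog, polarity, cilium, Hox, imprinted and matrix results. Each may therefore reflect the parental cultures, the loss of Macf1 or both.

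The clones were raised from single cells, so a mixture of cell types was unlikely by design. The lower mRNA of fibrillar matrix genes was still set against a lower share of fibroblasts. That alone would lower matrix genes by a similar factor. The 21 members of at least 100 CPM had a median log2 fold change of -1.25 (11 lower and 10 not passing). The median of the whole list was -2.73. Their interquartile range was 4.49, with a median standard error of 0.24. With 28.1% of all tested genes passing, a wide spread was likely beforehand whatever the cause. Members such as Col1a2 (1060 CPM in het and 0.816 CPM in knockout clones) reached 100 CPM through their het level alone. Other cell types also express some of these genes, such as Fn1. The spread therefore cannot tell whether a lower share of fibroblasts contributed, or whether the founding cells of the lines differed. The pattern did not rest on 1 unusual clone, since the median of the list stayed at -2.48 or below with any clone left out. The Macf1 genotype and another line of origin cannot be told apart here either.

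For Macf1, reassignment of reads between its transcripts alone would leave their sum unchanged, but the sum fell by 0.99 on the log2 scale (value -0.99). Whether the loss was even over the gene stays open, because the levels of its transcripts are estimated from shared reads and their standard errors do not cover errors in that assignment. The position of the loxP sites, which would bear on it, was not used here.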
